A study of Mus musculus with 14 samples.

How the data were processed

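Dark zone and light zone GC B cells were sorted from popliteal lymph nodes of immunized chimeric mice, mRNA was captured on oligo(dT) beads, and libraries were made with a variation of MARS-seq, per the labels' protocols. MARS-seq is a protocol for single cells that tags transcript ends with UMIs so that PCR copies can be removed. The submitters' processing notes name cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and DESeq and the mouse build mm10, with no role or order, and the counting settings are not given in the sources used here.

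The deposited UMI counts are whole numbers per gene symbol, 9969 genes in 14 libraries, not normalized. A second table holds deposited read counts for 11914 genes, of which 9954 symbols are shared with the first, and no shared entry has more UMIs than reads. The authors also deposited normalised values, a signal obtained by dividing the UMI counts by 1 size factor per library, regularised log2 values, log2 fold changes, p-values and adjusted p-values. UMI counts were analysed here, read counts served as an alternative, and the authors' fold changes and adjusted p-values served only for a count of shared calls. The deposited regularised log2 values were not used. The authors' mean of the normalised values over all libraries stands beside each of their comparisons with identical values, and 5 such repeated columns were mapped to no sample and not used. UMI counting removes PCR copies, so read counts, which keep them, overstate the number of independent molecules in libraries that gave few UMIs per read.

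Groups were taken from the genotype and zone labels. Genes were filtered with filterByExpr, which left 7999 genes holding 99.3% of the UMIs, scaled by TMM and fitted in edgeR 4.0.16 with a quasi-likelihood model of the 4 groups (robust, common biological coefficient of variation 32.3%) in R 4.3.3. Contrasts compared zones within genotypes, genotypes within zones, and the zone effects with each other. Adjusted p-values are Benjamini-Hochberg values over all tested genes of a contrast, with a threshold of 0.05. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over 24 lists), with camera using an estimated correlation and with fry, which tests whether a list's genes move on balance one way. Of 26 lists fixed, those of mitochondrially encoded and of immunoglobulin genes had 0 measured members and were not tested. By fry with adjustment, 3 lists passed in WT, 1 in SykY317F and 0 in each other contrast. Zone scores used log2 CPM with a prior count of 2 and exact permutation tests.

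The contrasts, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes the 10 genes with the smallest p in each direction among those past the threshold, the 3 smallest in each direction where fewer than 6 pass (for the difference of zone effects, up to 5 and otherwise 3), up to 4 members with the smallest p of each list described, and always Syk, Cbl, Cblb, Cxcr4, Cd83 and Cd86. The limit of 2 members shown per list was chosen later, and those shown are among the 2 with the smallest p. Predicted genes and pseudogenes with such symbols were counted but not named. Coordinates are those of GRCm38, the assembly of mm10, from its gene annotation, and all 236 genes that the rule can name had a position. For genes with 0 UMIs in a group, fold changes are bounds against 3 UMIs over the group, and with 1 to 3 UMIs a ratio with an exact binomial 95% interval is given.

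The steps were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Of the 2-fold genes 15 were recovered for the WT zones (7735 genes run), 5 for the SykY317F zones (7737), 15 for genotypes in DZ (7759), 6 for genotypes in LZ (7753) and 3 for the difference of zone effects (7759). Of the 4-fold genes 76, 50, 56, 53 and 26 were recovered, with 6, 5, 1, 0 and 3 calls among unchanged genes. A list shifted by 1.5-fold passed in each contrast and 0 others did. Genes were drawn independently of each other here, so this does not show how often lists of correlated genes pass by chance. Other splits of the real SykY317F DZ and WT DZ libraries called up to 17 lists.

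Alternatives set beforehand were DESeq2 size factors, scaling by library size, DESeq2 1.42.0's Wald test, no filter and a stricter filter (20 counts in 3 libraries), a fit of both groups alone, limma voom with sample quality weights, replicate number as a block, and leaving out each library. Added after seeing the data were read counts, thinning of all libraries to 149641 UMIs, leaving out the 4 libraries under 400000 UMIs or both libraries with the fewest, 1 surrogate variable from sva 3.50.0, exact permutation of list means, and removal of each library's trend with transcript GC content. Thinning was first run as a single draw, which proved the most extreme of a set for the zone score, and was replaced by the median of 21 draws. All pairs of libraries of a group differed by more than sampling noise, so none was counted as a repeat of another, though this does not show that they came from separate samples. WT DZ replicates 3 and 4 were the closest pair (chi-square per degree of freedom 2.02, next smallest 4.34). Figures were drawn with matplotlib 3.10.9.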

Results

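Germinal centre (GC) B cells were sorted by zone from popliteal lymph nodes of C57BL/6 mice and profiled by RNA sequencing. Each mouse was a chimera whose cells were 50% wild type (WT) and 50% SykY317F, and was immunized with the hapten-carrier conjugate NP-KLH 14 days before harvest. Syk is the kinase that relays signals from the B cell antigen receptor, and SykY317F is a variant of it with a tyrosine replaced by phenylalanine. In a GC, B cells divide and mutate their antibody genes in the dark zone (DZ) and meet antigen and helper T cells in the light zone (LZ). The 14 libraries form 4 groups, with 4 WT DZ, 4 WT LZ, 3 SykY317F DZ and 3 SykY317F LZ libraries. The labels do not state that the libraries of a group came from separate mice. The p-values of single genes and of exact permutation therefore measure the spread between these libraries. Camera p-values compare a list's genes with all other genes. With the preset correlation they assume how far genes vary together and do not measure the spread of a list between libraries.

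Depth differed between the groups. Unique molecular identifier (UMI) totals ran from 747948 to 1767898 in WT DZ, from 499443 to 1600902 in WT LZ and from 381954 to 1413310 in SykY317F DZ. In SykY317F LZ they ran from 149641 to 379125. The SykY317F LZ libraries gave 9.37 to 15.8 UMIs per 100 reads and SykY317F DZ replicate 4 gave 15.6, against 33.5 to 53.2 in the other 10 libraries. Genes with 0 UMIs made up 13.9% to 22.8% of the table in SykY317F LZ. A count of 3 UMIs corresponded to between 7.91 and 20.05 CPM (UMIs scaled to a common library total) in these libraries, so changes in weakly expressed genes were not detectable at this depth. Floors and counting intervals cover counting error only.

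**Figure D1:**
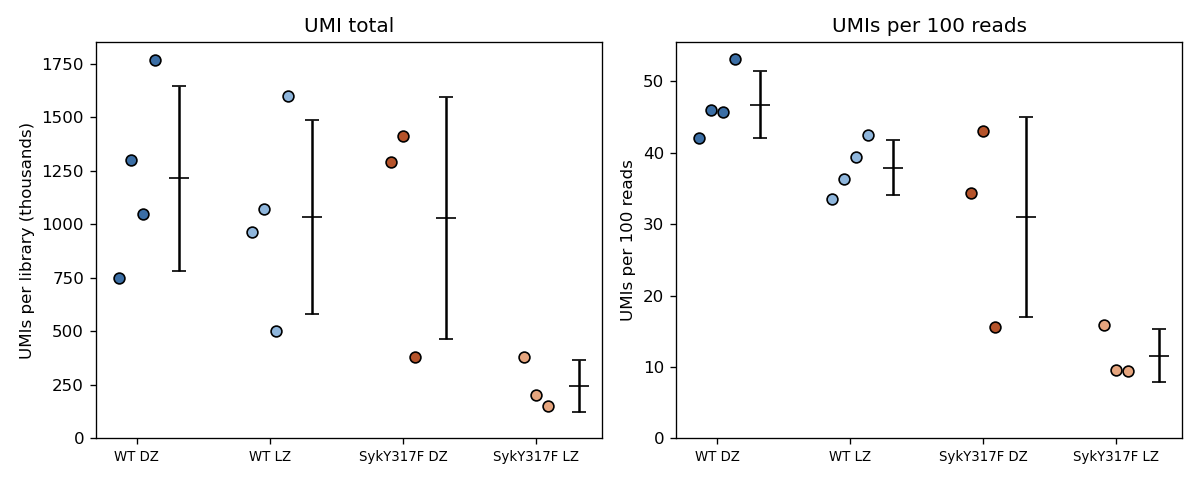
UMIs per library (left) and UMIs per 100 reads (right) for the 4 groups, with 1 point per library and the group mean with its SD beside the points. The 3 SykY317F LZ libraries have 149641 to 379125 UMIs and 9.37 to 15.8 UMIs per 100 reads.

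Syk mRNA (chromosome 13, 52582610 to 52648792, GRCm38) was measured at 517 ± 57.6 CPM in WT DZ (SD, n = 4), 422 ± 61.4 in WT LZ (n = 4), 547 ± 68.9 in SykY317F DZ (n = 3) and 414 ± 27.0 in SykY317F LZ (n = 3). Its genotype difference was a log2 fold change of 0.08 ± 0.20 (SE) in DZ and -0.03 ± 0.21 in LZ, neither of which passed in edgeR (adjusted p = 0.984 in LZ). A point mutant is transcribed, and libraries of this kind count transcript ends, so these values do not check the genotype labels.

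The first comparison set LZ against DZ in WT cells, the reference for what separates the zones. Cd72 (chromosome 4, 43447724 to 43455102), an inhibitory co-receptor of B cells, rose from 306 ± 33.7 CPM in DZ to 790 ± 252 in LZ (SD, n = 4 and 4). Gadd45g (chromosome 13, 51846675 to 51848475), a stress-inducible growth arrest gene, rose with a log2 fold change of 1.71 ± 0.33 (SE). Sh3bp2 (chromosome 5, 34525784 to 34563639), an adaptor of antigen receptor signalling, rose by 1.70 ± 0.34 on the log2 scale, and Cfp (chromosome X, 20925454 to 20931555), the complement factor properdin, by 1.37 ± 0.28. Gcsam (chromosome 16, 45610440 to 45622867), a signalling adaptor of GC B cells, fell from 192 ± 70.0 to 44.1 ± 21.7 CPM. Hmces (chromosome 6, 87913907 to 87936619), which shields abasic DNA sites, fell from 812 ± 185 to 300.0 ± 121 CPM.

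The other genes lower in WT LZ were Pafah1b3 (chromosome 7, 25295048 to 25297986), Rgcc (chromosome 14, 79288750 to 79301635), Myl4 (chromosome 11, 104546017 to 104587215), Lipc (chromosome 9, 70798128 to 70952221), Smco4 (chromosome 9, 15468440 to 15545260), Gadd45b (chromosome 10, 80930091 to 80932204), Cmpk1 (chromosome 4, 114960613 to 114987228) and Scn11a (chromosome 9, 119753763 to 119825456). Pafah1b3 had a log2 fold change of -2.05 ± 0.27, Rgcc -2.07 ± 0.33, Myl4 -1.57 ± 0.25 and Lipc -1.66 ± 0.28. Smco4 had a log2 fold change of -1.46 ± 0.27, Gadd45b -1.01 ± 0.20 and Cmpk1 -1.23 ± 0.25. Scn11a had 2 UMIs in all WT LZ libraries together and 88 in WT DZ, a ratio of 37.4 (95% counting interval 10.1 to 314). Cd72 overlaps Tesk1 and Myl4 overlaps Cdc27 in the annotation, so their counts are uncertain where the authors' counting could split or share them.

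In all, 15 of 7999 tested genes changed in WT, 4 higher and 11 lower in LZ (edgeR, adjusted p from 0.00146 to 0.0458 over the named genes), and 678 had an unadjusted p under 0.05 where 400.0 were due by chance alone. Of the 15, 1 is a transcript without a gene name. Cd83, a surface marker by which LZ cells are known, had a log2 fold change of 0.94 ± 0.24 and Cxcr4, the chemokine receptor that marks DZ cells, -0.62 ± 0.30, and neither passed (adjusted p = 0.106 and 0.588). Cd86 had 0.37 ± 0.48, Cbl -0.71 ± 0.53 and Cblb -0.74 ± 0.90, with adjusted p of 0.879, 0.763 and 0.872. DESeq2's Wald test called 98 genes, limma voom with sample quality weights 295, a fit of both groups alone 6 and the read counts, chosen after seeing the data, 0. The count was 6 without WT DZ replicate 3, 7 without WT LZ replicate 1, 1 (Pafah1b3) without WT LZ replicate 2, 26 without WT LZ replicate 3, and 9 without SykY317F LZ replicate 1 or replicate 2.

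Of 24 gene lists, 11 differed between the zones in WT by camera with its preset correlation, 6 higher and 5 lower in LZ. The LZ programme (activation and survival genes) was higher, with 33 of its 35 members on that side, a median log2 fold change of 0.84 and adjusted p = 6.23e-18. Of them 1 passed over all genes and 10 when adjusted over the list alone. Its examples were Cd72 and Cd40, the receptor for T cell help, at 0.94 ± 0.20. All 14 NF-kB and CD40 targets were on the higher side (median 0.56, adjusted p = 4.05e-08), 3 of them past the threshold when adjusted over the list alone. Nfkb2 was at 0.79 ± 0.24. Both lists also passed with an estimated correlation (adjusted p = 0.00253 for each).

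The antigen receptor early response list had 10 of 11 members higher (median 1.12, adjusted p = 0.000169), with Egr2, an immediate early transcription factor, at 1.499 ± 0.47 and Pim1, a survival kinase, on the other side at -1.20 ± 0.29. The MHC class II presentation list had 11 of 13 higher (median 0.35, adjusted p = 0.000633), with Ifi30 at 0.74 ± 0.24 and H2-DMb2 at 0.99 ± 0.38. The naive and memory B cell list had 11 of 13 higher (median 0.87, adjusted p = 5.71e-05), with Ccr6 at 1.65 ± 0.38 and Fcer2a at 0.84 ± 0.24. Beside these, T cell markers had 6 of 7 higher (median 1.64, adjusted p = 0.00263), with Cd4 at 2.34 ± 0.79 and Lat at 0.81 ± 0.31. With an estimated correlation the first 3 had adjusted p = 0.214 and the T cell list adjusted p = 0.260. When adjusted over the list alone, 2 early response, 0 MHC class II, 5 naive and memory and 3 T cell genes passed as higher, and 1 early response and 1 naive and memory gene as lower.

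The GC B cell identity list had all 13 members lower in WT LZ (median -0.58, adjusted p = 4.26e-08; adjusted p = 0.0629 with an estimated correlation), with Pou2af1, a B cell transcriptional coactivator, at -1.05 ± 0.27. The DZ programme had 7 of 10 lower (median -0.52, adjusted p = 0.00155), with Gcsam at -2.09 ± 0.36. G2 and mitosis genes had 21 of 29 lower (median -0.44, adjusted p = 2.84e-06), with Cdc20 at -1.09 ± 0.27 and Cenpa at -0.90 ± 0.23. Oxidative phosphorylation had 34 of 38 lower (median -0.30, adjusted p = 5.63e-05), with Atp5k at -0.86 ± 0.27 and Sdhb at -0.59 ± 0.19. S phase had 20 of 26 lower (median -0.30, adjusted p = 0.0144), with Rfc4 at -0.94 ± 0.32 and Ccne1 on the other side at 0.57 ± 0.29. With an estimated correlation the adjusted p were 0.214 for the DZ programme and oxidative phosphorylation, 0.311 for G2 and mitosis and 0.421 for S phase. When adjusted over the list alone, 3 identity, 2 DZ programme, 7 G2 and mitosis, 0 oxidative phosphorylation and 0 S phase genes passed. The S phase list no longer passed without WT DZ replicate 3 (adjusted p = 0.120), WT LZ replicate 1 (0.0776) or WT LZ replicate 2 (0.202).

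The second comparison set LZ against DZ in SykY317F cells. Ffar2 (chromosome 7, 30818031 to 30823775), a receptor for short-chain fatty acids, rose from 9.7 ± 1.3 CPM in DZ to 85.7 ± 20.5 in LZ (SD, n = 3 and 3; adjusted p = 0.0148). In WT, Ffar2 was at 15.3 ± 7.9 CPM in DZ and 46.1 ± 11.7 in LZ. It did not pass there in the main fit, but did with GC trends removed (edgeR, adjusted p = 0.0309), an alternative added after seeing the data. Gadd45b fell from 523 ± 89.8 to 181 ± 15.7 CPM (adjusted p = 0.0154), and Nr3c1 (chromosome 18, 39410545 to 39519421), the glucocorticoid receptor, fell from 83.4 ± 5.7 to 20.9 ± 5.3 CPM (adjusted p = 0.0484). Nr3c1 had only 9, 3 and 3 UMIs in the SykY317F LZ libraries. The next genes by p within each direction did not pass: S1pr3 at 1.55 ± 0.35 and Arid3b at 1.11 ± 0.25 on the higher side, and Myl4 at -1.69 ± 0.33 on the lower (log2 fold change ± SE). Cd83 had 1.06 ± 0.28, Cd86 1.56 ± 0.61, Cxcr4 0.23 ± 0.35, Syk -0.40 ± 0.23 and Cbl -0.61 ± 0.83, none of them past the threshold. Cblb had 2 UMIs in SykY317F LZ and 29 in SykY317F DZ, a ratio of 3.43 (95% counting interval 0.868 to 29.7). Of the 29, 27 were in SykY317F DZ replicate 2, and without that library the fitted log2 fold change turned to 1.33.

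These 3 genes were the ones called by edgeR, 1 higher and 2 lower, with 821 at an unadjusted p under 0.05. DESeq2's Wald test called 39, scaling by library size only 9 and a fit of both groups alone 1. Scaling by library size only moved the median of all genes to -0.19, from -0.04 with TMM scaling, and the changes given are relative to the TMM scale. Among alternatives chosen after seeing the data, read counts gave 20, a surrogate variable 14 and leaving out both libraries with the fewest UMIs 0. The count was 8 without WT DZ replicate 5, 10 without SykY317F DZ replicate 2, 5 without SykY317F LZ replicate 4, 1 without SykY317F LZ replicate 1, and 0 without SykY317F DZ replicate 1, SykY317F DZ replicate 4 or SykY317F LZ replicate 2.

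By camera, 7 lists differed between the zones in SykY317F, 4 higher and 3 lower in LZ, and none of them passed with an estimated correlation. The LZ programme had 26 of 35 members higher (median 0.35, adjusted p = 4.14e-06), with Icam1, an adhesion molecule, at 0.85 ± 0.26. NF-kB and CD40 targets had 12 of 14 higher (median 0.39, adjusted p = 0.00112), with Nfkb2 at 0.75 ± 0.29. Both had adjusted p = 0.0959 with an estimated correlation. MHC class II presentation had 11 of 13 higher (median 0.50, adjusted p = 8.77e-05), with H2-DMb2 at 1.84 ± 0.48 and Ifi30 at 0.87 ± 0.28. G2 and mitosis genes had all 29 lower (median -0.84, or -0.82 with the 2 members at 0 UMIs in LZ set at their bound; adjusted p = 2.77e-11), with Ccnb2 at -2.62 ± 0.57 and Ube2c at -1.82 ± 0.42. Both lists had adjusted p = 0.236 with an estimated correlation. S phase genes had 23 of 26 lower (median -0.38, adjusted p = 0.00619; 0.614 with an estimated correlation), with Rfc4 at -1.24 ± 0.49 and Pola1 at -1.56 ± 0.68.

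The ribosomal protein list had 59 of 69 members higher in SykY317F LZ (median 0.35, adjusted p = 7.16e-07; 0.605 with an estimated correlation), with Rpl24 at 1.09 ± 0.35. Rpl15 had 0 UMIs in SykY317F LZ and 61 in SykY317F DZ, at least 4.81-fold lower against a floor of 3 UMIs over the group. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain. Beside these, myeloid markers had all 7 members lower in LZ (median -2.49, adjusted p = 5.48e-06; 0.177 with an estimated correlation), with Tyrobp at -2.94 ± 0.86 and C1qc at 1 UMI in LZ and 63 in DZ, a ratio of 14.9 (95% counting interval 2.58 to 598). When adjusted over the list alone, 1 LZ programme and 2 MHC class II genes passed as higher, and 5 G2 and mitosis, 5 myeloid and 1 ribosomal protein gene as lower, against 0 NF-kB and 0 S phase genes. The S phase call ended without both libraries with the fewest UMIs (adjusted p = 0.403), which was tried after seeing the data.

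A zone score was computed per library as the mean log2 CPM of the LZ programme (35 genes) minus that of the DZ programme (10 genes). It averaged -0.32 ± 0.21 in WT DZ and 0.94 ± 0.23 in WT LZ (SD, n = 4 each), and 0.03 ± 0.50 in SykY317F DZ and 0.90 ± 0.57 in SykY317F LZ (SD, n = 3 each). The WT zones differed by 1.25 (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 libraries allow). The SykY317F zones differed by 0.87 (exact permutation p = 0.20, where 3 against 3 cannot go below 0.10). Genotypes differed by 0.35 in DZ (exact permutation p = 0.343) and by -0.03 in LZ (exact permutation p = 0.857). The difference of the zone differences was -0.39 (exact permutation p = 0.358 over 1225 arrangements). With members of at least 20 counts on average, the DZ difference was 0.44 (exact permutation p = 0.0286) and the LZ difference turned to 0.017, and the LZ difference was also positive without WT LZ replicate 2 (0.058) or SykY317F LZ replicate 4 (0.24).

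**Figure D2:**
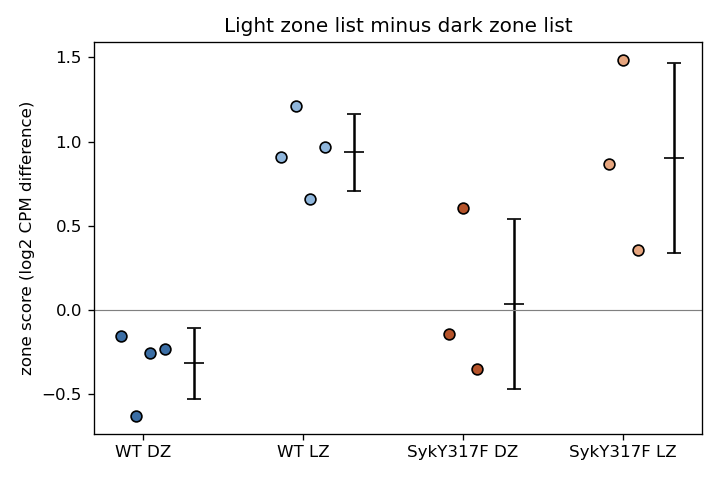
Zone score (log2 CPM difference between the LZ and DZ programmes) of each library by group, with 1 point per library and the group mean with its SD beside the points. WT DZ averages -0.32 and WT LZ 0.94, and the SykY317F groups average 0.03 and 0.90 with a wider spread.

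Across the 7999 tested genes, the SykY317F zone effects had a slope of 0.51 on the WT ones and a reverse slope of 0.17, with Pearson r = 0.296 and 61.3% of genes on the same side. Genes are not independent replicates, so no p is given. Over the 99 genes of the zone and cell cycle lists the slope was 0.65, the reverse slope 0.28 and r = 0.423. In simulated counts with a true slope of 0.50 the recovered slope was 0.28 with a reverse slope of 0.22, so noise flattens such slopes. The true WT effects simulated were spread about as widely as the observed WT log2 fold changes (SD 0.51), which include noise. The amount of flattening therefore does not carry over to the real slopes. The slope over the 99 genes was 1.01 without SykY317F DZ replicate 2 and 0.44 without SykY317F LZ replicate 2.

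The third comparison set SykY317F against WT in DZ, and no gene passed. The genes with the smallest p on the higher side were C1qb (chromosome 4, 136880126 to 136886200), a complement component made by macrophages, at 37.2 ± 21.5 CPM in SykY317F against 6.2 ± 1.9 in WT (SD, n = 3 and 4), Igfbp4 (chromosome 11, 99040005 to 99052655) with a log2 fold change of 4.19 ± 0.95 (SE), and S1pr1 (chromosome 3, 115710433 to 115715055), the receptor that guides lymphocytes out of lymph nodes, at 51.6 ± 34.8 against 14.6 ± 3.4. On the lower side they were Rps4l (chromosome 6, 148354656 to 148355596), annotated as a transcribed pseudogene that overlaps Tmtc1, so that its counts are uncertain, at -4.19 ± 0.95 (log2 fold change ± SE), Arl6ip6 (chromosome 2, 53192084 to 53219221) at -1.39 ± 0.41 and Nrgn (chromosome 9, 37544493 to 37552745) at -0.85 ± 0.26. The smallest adjusted p was 0.628. Igfbp4 had 0, 1, 3 and 0 UMIs in the WT DZ libraries and 6, 30 and 12 in the SykY317F DZ ones. Rps4l had 0, 4 and 0 UMIs in SykY317F DZ and 7, 32, 10 and 83 in WT DZ. Both fold changes therefore rest on counts near the floor in 1 group. Cxcr4 had 0.46 ± 0.32, Cd83 0.40 ± 0.26, Cd86 -0.67 ± 0.54, Cbl -0.81 ± 0.58 and Cblb -0.75 ± 0.99, none past the threshold. edgeR called 0 genes, with 305 at an unadjusted p under 0.05, DESeq2's Wald test called 2 and limma voom with sample quality weights 4.

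By camera 13 lists differed, 8 higher and 5 lower in SykY317F DZ. Naive and memory B cell genes had 11 of 13 members higher (median 1.55, adjusted p = 5.90e-11; 0.0707 with an estimated correlation), with Klf2, a quiescence factor, at 1.65 ± 0.38. Markers of other cell types moved with them. T cell markers had all 7 higher (median 2.61, adjusted p = 4.13e-10), with Cd4 at 2.66 ± 0.83 and Lat at 1.18 ± 0.33, and myeloid markers had all 7 higher (median 0.72, adjusted p = 7.35e-10), with C1qc at 2.93 ± 0.72. Both had adjusted p = 0.0421 with an estimated correlation. In the WT DZ libraries Cd4 had 1, 1, 4 and 5 UMIs, Cd8b1 3, 0, 1 and 0 and Thy1 2, 1, 11 and 2, against 27, 22, 29 and 56 for Lat. Such low counts limit how well the size of the T cell median is measured. Stromal and endothelial markers had 3 of 3 higher (median 0.72, adjusted p = 0.0103; 0.142 with an estimated correlation), with Pecam1 at 0.72 ± 0.35 and Mfge8 at 0.83 ± 0.45. The antigen receptor early response list had all 11 higher (median 0.77, adjusted p = 0.000138; 0.191 with an estimated correlation), with Egr3 at 2.16 ± 0.73 and Ier2 at 1.73 ± 0.56. The dissociation and heat shock list had 6 of 7 higher and did not pass (median 0.57, adjusted p = 0.0687; 0.361 with an estimated correlation). In every group replicate 2 had the highest mean log2 CPM on both lists, for the early response 7.27 in SykY317F DZ.

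The LZ programme had 27 of 35 members higher in SykY317F DZ (median 0.40, adjusted p = 0.000151; 0.142 with an estimated correlation), with Ccnd2 at 1.79 ± 0.53. Migration and adhesion had 11 of 16 higher (median 0.19, adjusted p = 0.0176; 0.142 with an estimated correlation), with S1pr1 at 1.89 ± 0.44, and ribosomal proteins 47 of 69 (median 0.08, adjusted p = 0.0369; 0.657 with an estimated correlation), with Rpl10a at 0.49 ± 0.27 and Rpl6 at 0.53 ± 0.30. S phase genes had 25 of 26 lower (median -0.48, adjusted p = 1.67e-09; 0.132 with an estimated correlation), with Rrm2 at -0.99 ± 0.41 and Pcna at -0.74 ± 0.32. G2 and mitosis genes had all 29 lower (median -0.38, adjusted p = 4.90e-05), with Birc5 at -0.51 ± 0.30 and Ttk at -1.21 ± 0.74, and oxidative phosphorylation had 31 of 38 lower (median -0.23, adjusted p = 0.0160), with Sdhb at -0.37 ± 0.21 and Atp5c1 at -0.36 ± 0.23. Both had adjusted p = 0.361 with an estimated correlation. GC B cell identity had all 13 lower (median -0.41, adjusted p = 0.000116; 0.142 with an estimated correlation), with Bcl6, the master regulator of GC B cells, at -0.53 ± 0.24. DNA repair and hypermutation had 14 of 17 lower (median -0.27, adjusted p = 0.0176; 0.191 with an estimated correlation), with Lig4 at -0.93 ± 0.46.

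When adjusted over the list alone, 5 naive and memory, 5 T cell, 3 myeloid, 2 early response and 1 migration gene passed as higher, and 0 genes of the other 8 lists passed. Without SykY317F DZ replicate 2, 7 lists passed, and the early response median turned to -0.06 (adjusted p = 0.832) while the LZ programme (adjusted p = 0.377), G2 and mitosis (0.0743), oxidative phosphorylation (0.0779), migration (0.331) and ribosomal proteins (0.0779) no longer passed. The naive and memory median fell to 0.52 without that library and the myeloid median to 0.27 without SykY317F DZ replicate 4, and both lists still passed (adjusted p = 4.97e-05 and 1.98e-06). Oxidative phosphorylation also ended without WT DZ replicate 3 (0.143) or SykY317F DZ replicate 1 (0.392), DNA repair without WT DZ replicate 3 (0.0998), WT DZ replicate 4 (0.0730) or SykY317F DZ replicate 1 (0.05002), migration without WT DZ replicate 5 (0.140), and stromal markers without WT DZ replicate 3 (0.0672) or SykY317F DZ replicate 1 (0.0766). Ribosomal proteins ended without WT DZ replicate 2 (0.0871), WT DZ replicate 4 (0.0711), WT DZ replicate 5 (0.0809) or SykY317F LZ replicate 1 (0.0615), and turned to a median of -0.05 without SykY317F DZ replicate 4 (0.552).

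The fourth comparison set SykY317F against WT in LZ, where the SykY317F libraries had fewer UMIs than any WT library, and no gene passed. On the higher side Ost4 (chromosome 5, 30906516 to 30907807), a subunit of the glycosylation machinery, was at 251 ± 83.6 CPM in SykY317F against 101 ± 17.2 in WT (SD, n = 3 and 4) and Rpl36al (chromosome 12, 69182734 to 69184067) at 618 ± 186 against 233 ± 109. On the lower side Nr3c1 was at 20.9 ± 5.3 (9, 3 and 3 UMIs) against 80.6 ± 10.4 CPM, Gar1 (chromosome 3, 129824912 to 129831407), a nucleolar protein, had a log2 fold change of -1.74 ± 0.33 (SE), and E2f8 (chromosome 7, 48866429 to 48882073), a cell cycle transcription factor, had 1 UMI against 130, a ratio of 23.0 (95% counting interval 4.05 to 914). All 5 had adjusted p = 0.111. Cxcr4 had 1.31 ± 0.33 (log2 fold change ± SE, adjusted p = 0.154), Cd83 0.51 ± 0.26, Cd86 0.52 ± 0.55 and Cbl -0.72 ± 0.79, none past the threshold, and Cblb had 2 UMIs against 42, a ratio of 3.71 (95% counting interval 0.965 to 31.6). Of the 42, 37 were in WT LZ replicate 5, and without that library the fitted log2 fold change of Cblb turned to 0.53. Rpl36al shares sequence with Rpl36a, and Ost4 overlaps Agbl5, so their counts are uncertain.

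edgeR called 0 genes, with 785 at an unadjusted p under 0.05, while DESeq2's Wald test called 42, limma voom with sample quality weights 0 and scaling by library size only 1, with a median of all genes at -0.16. Chosen after seeing the data, read counts gave 54, removal of each library's GC trend 23 and a surrogate variable 7. The count was 5 without WT DZ replicate 5, 1 without WT LZ replicate 2 and 3 without WT LZ replicate 3.

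By camera 3 lists differed in LZ, and none passed with an estimated correlation. G2 and mitosis genes had all 29 members lower in SykY317F (median -0.98, or -0.87 with members at 0 UMIs at their bound; adjusted p = 3.75e-09), with Top2a at -1.36 ± 0.38 and Kif23 at -1.57 ± 0.46. S phase genes had 23 of 26 lower (median -0.72, adjusted p = 6.28e-07), with E2f1 at -1.40 ± 0.38 and Gins2 at -1.06 ± 0.34. Both had adjusted p = 0.671 with an estimated correlation. Ribosomal proteins had 56 of 69 higher (median 0.34, adjusted p = 2.06e-09; 0.692 with an estimated correlation), with Rpl23 at 1.21 ± 0.27, and Rpl15 had 0 UMIs against 63 in WT, at least 3.71-fold lower. When adjusted over the list alone, 5 G2 and mitosis and 1 S phase gene passed as lower, and 11 ribosomal protein genes as higher and 1 as lower. Beside them the T cell list (median -0.08) and the myeloid list (median -0.77) did not pass. The number of lists was 5 without SykY317F LZ replicate 1 or replicate 4.

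**Figure D3:**
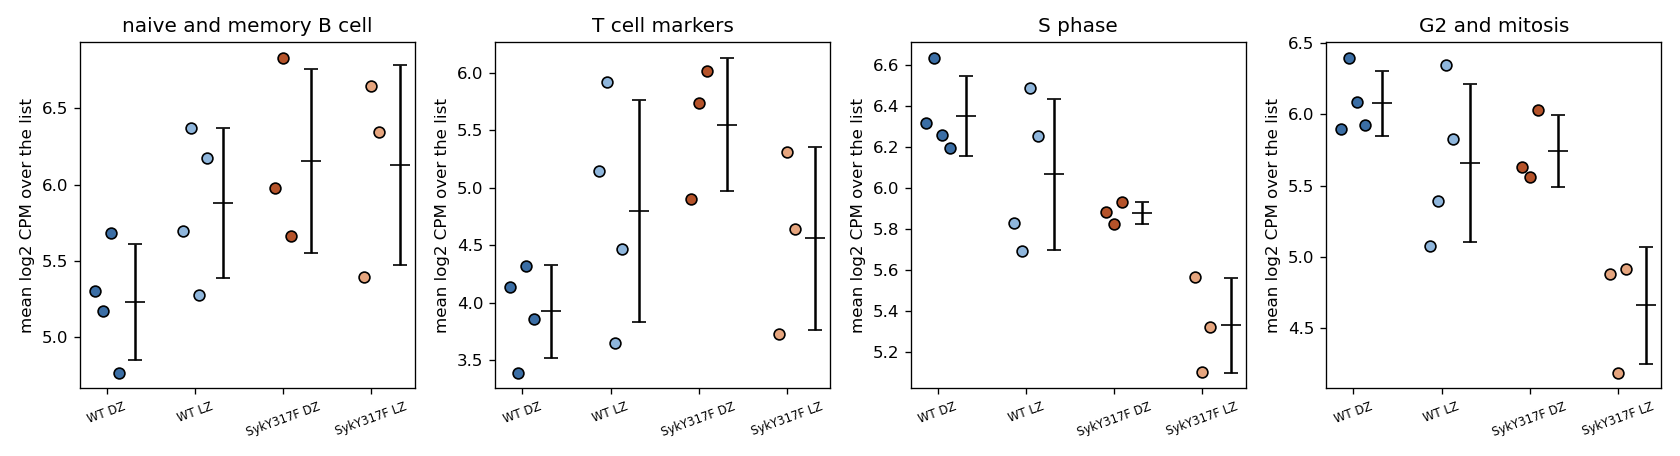
Mean log2 CPM of 4 gene lists in each library by group, with 1 point per library and the group mean with its SD beside the points. All 7 T cell markers had a higher fitted value in SykY317F DZ than in WT DZ, and all 29 G2 and mitosis genes a lower one in SykY317F LZ than in WT LZ.

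The last comparison tested whether the zone effect differed between the genotypes, and no gene passed. On the higher side Ndufs4 (chromosome 13, 114287795 to 114388094) had a difference of 1.78 ± 0.45 (log2, SE), E2f3 (chromosome 13, 29906575 to 29986064) 2.25 ± 0.61 and Cks2 (chromosome 13, 51645232 to 51650662) 2.26 ± 0.64. On the lower side Nr3c1 had -1.82 ± 0.42 and Herc1 (chromosome 9, 66350412 to 66508775) -2.37 ± 0.51, while Setd1b (chromosome 5, 123142040 to 123168630) had 3, 0 and 0 UMIs in the SykY317F LZ libraries. In the same libraries Nr3c1 had 9, 3 and 3 UMIs and Herc1 6, 1 and 3. The smallest adjusted p was 0.535. Cxcr4 had 0.85 ± 0.46, Cd86 1.19 ± 0.77, Cd83 0.12 ± 0.37, Syk -0.11 ± 0.29, Cbl 0.09 ± 1.02 and Cblb -0.61 ± 1.98, none past the threshold. edgeR called 0 genes, with 384 at an unadjusted p under 0.05, and DESeq2's Wald test and limma voom with sample quality weights also called 0.

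By camera 8 lists had a zone effect that differed by genotype, 3 higher and 5 lower, and none passed with an estimated correlation. The antigen receptor early response was lower (median -1.44, adjusted p = 0.0142), with Egr3 at -2.79 ± 1.20 and Egr2 at -1.54 ± 0.80. G2 and mitosis was lower (median -0.63, adjusted p = 0.00160), with Ccnb2 at -1.45 ± 0.69 and Ube2c at -1.01 ± 0.51, and naive and memory B cell genes were lower (median -0.73, adjusted p = 0.0124), with S1pr1 at -2.32 ± 0.72 and Bcl2 at -1.83 ± 0.91. GC B cell identity was higher (median 0.59, adjusted p = 0.0104), with Fas at 1.299 ± 0.63 and Rgs13 at 2.83 ± 1.89 (-0.93 without SykY317F LZ replicate 2), ribosomal proteins were higher (median 0.20, adjusted p = 0.000282), with Rpl23 at 1.14 ± 0.39, and these 5 lists had adjusted p = 0.603 with an estimated correlation. Oxidative phosphorylation was higher (median 0.21, adjusted p = 0.000282; 0.601 with an estimated correlation), with Uqcrh at 1.36 ± 0.47 and Ndufc1 at 1.48 ± 0.52. Beside these, T cell markers (median -2.70, adjusted p = 0.000282; 0.555 with an estimated correlation) and myeloid markers (median -2.21, adjusted p = 1.16e-05; 0.424 with an estimated correlation) were lower, with Lat at -1.56 ± 0.51, and Cd4 with 0, 0 and 1, C1qa with 0, 2 and 0 and C1qc with 1, 0 and 0 UMIs in the SykY317F LZ libraries. When adjusted over the list alone, 2 T cell and 3 myeloid genes passed as lower and 0 genes of the other 6 lists passed.

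Leaving out 1 library ended several of these calls, and 5 lists passed without WT LZ replicate 2 or SykY317F DZ replicate 2. The early response ended without WT DZ replicate 5 (adjusted p = 0.0534), WT LZ replicate 2 (0.0510), SykY317F DZ replicate 2 (0.813), SykY317F LZ replicate 1 (0.177) or SykY317F LZ replicate 4 (0.109), and G2 and mitosis without WT LZ replicate 3 (0.181), SykY317F DZ replicate 4 (0.0721) or SykY317F LZ replicate 2 (0.110). Naive and memory genes ended without WT DZ replicate 5 (0.158), WT LZ replicate 2 (0.0870), WT LZ replicate 5 (0.0540), SykY317F DZ replicate 2 (0.355) or SykY317F LZ replicate 1 (0.366), and GC B cell identity without WT LZ replicate 2 (0.0901), SykY317F DZ replicate 2 (0.0747) or SykY317F LZ replicate 4 (0.107). Ribosomal proteins ended without SykY317F DZ replicate 1 (0.109) and turned to a median of -0.03 without SykY317F LZ replicate 2 (0.273).

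The authors' deposited table calls 78 genes between the WT zones, 22 between the SykY317F zones, 18 between genotypes in DZ and 25 in LZ. All 15 genes called here in WT and all 3 in SykY317F are among them, and 15 of the 18 in DZ were tested here. In the authors' deposited table, of the 78 genes 31 were higher and 47 lower, and fold changes over all genes tested here had the same sign in 98.2% to 99.1% of genes.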

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

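The thinning of counts to equal UMI totals, the test of 1 library alone (read from fits set beforehand), the test for exchanged labels, the second count of splits (with GC trends removed) and the fits with GC trends removed were tests chosen only after the results were seen. In 2 of 54 sets of 4 library values, 1 library stood far from the other 3, and chance alone gives this in about 1 of 20 sets. The mean log2 CPM of the plasma cell list was 6.28 in WT DZ replicate 5 and 6.62 to 6.65 in the other WT DZ libraries. That of the ribosomal protein list was 11.3 in WT LZ replicate 2 and 10.7 to 10.8 in the other WT LZ libraries.

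The zone effect differed between the genotypes by camera with its preset correlation for 8 lists. The median differences were -1.44 for the antigen receptor early response, -0.63 for G2 and mitosis, -0.73 for naive and memory B cell genes, 0.59 for GC B cell identity, 0.21 for oxidative phosphorylation, -2.70 for T cell markers, -2.21 for myeloid markers and 0.20 for ribosomal proteins. None of the 8 passed with an estimated correlation (adjusted p from 0.424 to 0.603).

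T cell, myeloid and naive and memory B cell genes were higher in SykY317F DZ than in WT DZ by camera with its preset correlation, but with an estimated correlation the naive and memory list did not pass (adjusted p = 0.0707), and 2 of 35 splits called at least 13 lists, so chance is not excluded. GC content of the transcripts as the whole cause is excluded, since with GC trends removed the largest adjusted p of the 3 lists was 6.49e-09. All 3 lists also passed camera without each SykY317F DZ library (largest adjusted p 4.97e-05). For the T cell and myeloid lists, each SykY317F DZ library had a higher mean log2 CPM than every WT DZ library. A single SykY317F DZ library as the whole cause is excluded for both lists, although the myeloid median fell from 0.72 to 0.27 without replicate 4. For the naive and memory list a single library is not excluded. Its median fell from 1.55 to 0.52 without replicate 2, and its mean in replicate 4 (5.66) lay within the WT DZ range (4.77 to 5.68). RNA from other cells may contribute, since second T cell and myeloid lists, written down before this test, were also higher (10 of 10 and 9 of 10 members, medians of 1.27 and 0.40), though their abundant members Gimap6, Apoe, Cybb and Cst3 had only 0.17, 0.18, 0.03 and -0.20, from WT levels high enough to hide a small share. The gap in UMI totals as the whole cause is excluded only for the naive and memory genes kept after thinning, 7 of 13 in the typical draw. They passed camera with a median log2 fold change of 0.92 (21 of 21 draws tested, median adjusted p 0.000156). Thinning cannot decide this cause for the T cell list, tested in 8 draws (median adjusted p 0.0266, median log2 fold change 0.46 on 2 members), or the myeloid list, tested in 0. SykY317F DZ replicates 1 and 2 had 1293407 and 1413310 UMIs, within the WT DZ range. Their T cell list means of 4.90 and 5.73 log2 CPM lay above every WT DZ library (at most 4.32). Without replicate 4 the T cell median was 2.53 (camera, adjusted p = 1.62e-10). For the T cell list these values argue against the gap in UMI totals as the whole cause. The sort for GC B cells should remove T cells and macrophages, and a biological difference between the genotypes stays open and untested, as does the unequal yield of UMIs per read.

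S phase and G2 and mitosis genes were lower in SykY317F LZ than in WT LZ. The gap in UMI totals as the whole cause is excluded only for the members kept after thinning all libraries to equal UMIs. In the typical draw 18 of 26 S phase and 17 of 29 G2 and mitosis genes were kept. Their median log2 fold changes were -0.70 and -0.80, and the larger median adjusted p of both lists was 9.39e-06 (camera, preset correlation). A loss of weakly expressed genes as the whole cause is excluded too. Random lists matched on mean expression had a typical median of -0.064 for S phase and -0.054 for G2 and mitosis, and 0 of 10000 was as low as either list. GC content as the whole cause is also excluded, since with GC trends removed the larger adjusted p was 1.53e-06 and the medians were -0.58 and -0.84. With an estimated correlation neither list passed (adjusted p = 0.671), and other splits of the same libraries called as many lists, as given with the splits, so a chance difference between these 7 libraries stays open, as does their unequal yield of UMIs per read, which thinning does not match. A biological difference between the genotypes may also contribute and was not tested apart from this.

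Exchanging WT DZ replicate 5 and WT LZ replicate 5 called 290 genes, against 15 between the real zones, which points to a structure among the libraries other than zone. A full exchange of labels is excluded, since WT DZ replicate 5 and WT LZ replicate 5 had zone scores of -0.23 and 0.97, each within the range of its own zone, but in WT DZ replicate 5 the mean log2 CPM of the DZ programme (5.69), GC B cell identity (6.72) and MHC class II presentation (10.1) lay within the range of the WT LZ libraries, while the LZ programme (5.45), NF-kB and CD40 targets (6.06) and naive and memory B cell genes (4.77), which added LZ RNA would raise, were the lowest of the WT libraries. The GC content of the transcripts may account for part of it: the 266 genes lower under the exchange had a median GC content of 42.2% and the 24 higher ones 58.7%, a difference of -16.6 percentage points. The slope of log2 CPM per 10 points of GC ran from -0.60 in WT DZ replicate 4 to 0.58 in WT LZ replicate 1. With GC trends removed the same exchange called 58 genes, 45 of them among the 290, and the median absolute log2 fold change of the 290 fell from 1.83 (median SE 0.43) to 1.20 (0.37), so the structure remained in part, and no biological explanation was tested.

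Splits of the same libraries into groups of the same sizes were counted for each comparison, the real split included in each count. For the WT zones 2 of 35 splits called at least 15 genes (highest other 290) and 6 of 35 at least 11 lists (highest other 13), so chance is not excluded. For the SykY317F zones 10 splits are too few for a share under 0.05: 1 split called 3 genes (highest other 0) and 4 called at least 7 lists (highest other 10). Where the real split called 0 genes, the count of splits was fixed before it ran and decides nothing: 35 of 35 for genotypes in DZ (highest other 114, with WT DZ replicate 5 and SykY317F DZ replicate 2 exchanged), 35 of 35 in LZ (highest other 1) and 100 of 100 for the difference of zone effects (highest other 16). For lists, chance is not excluded in these 3 comparisons: 2 of 35 splits called at least 13 lists for genotypes in DZ (highest other 17), 22 of 35 at least 3 in LZ (highest other 10) and 18 of 100 at least 8 for the difference (highest other 12). With GC trends removed, 2 of 35 splits of the WT libraries called at least 47 genes (highest other 58, the exchange above) and 3 of 35 at least 11 lists (highest other 14), so chance is not excluded. For the SykY317F zones the real split called 5 genes (highest other 0) and 7 lists (highest other 10), again with too few splits, and for genotypes in DZ 0 genes (highest other 54) and 12 lists, as many as in 2 of 35 splits (highest other 12), so chance is not excluded for these lists. For genotypes in LZ 1 of 35, the smallest share possible, called 23 genes (highest other 4) and 16 of 35 at least 4 lists (highest other 11). Chance is not excluded for the lists. Nor is it excluded for the gene count, since 1 such share can arise by chance among several counts made after the data were seen. That count comes from an added alternative in which depth still differs between the genotypes.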

How the results depend on the processing

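Read counts, thinning, the surrogate variable, GC trend removal, exact permutation of list means, and leaving out the 4 libraries under 400000 UMIs or both with the fewest were chosen only after the results were seen, and the cause of the differences given here was not tested. Among named genes and single lists, 4438 values under an alternative kept their direction and side of the threshold, 276 lost and 79 gained a call, and 43 changed sign. Depth limits the SykY317F LZ libraries most. Leaving out the immunoglobulin genes gave no value, since 0 were measured, nor did leaving out the libraries under 400000 UMIs where it emptied a group, or a block within genotype for genotype comparisons.

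In the WT zones, 15 genes became 98 with DESeq2's Wald test, 295 with limma voom and sample quality weights (0.209 for WT DZ replicate 5, 2.38 for WT DZ replicate 3), 6 with both groups alone, 0 with read counts, 4 without the libraries under 400000 UMIs, 9 without both with the fewest UMIs, 38 with a surrogate variable, 47 with GC trends removed, and 1 to 26 without each library. In the SykY317F zones, 3 became 39 with the Wald test, 9 with library size only, 1 with both groups alone, 20 with read counts, 0 without both libraries with the fewest UMIs, 14 with a surrogate variable, 5 with GC trends removed and 0 to 10 without each library. Between genotypes in DZ, 0 became 2 with the Wald test and 4 with limma voom, and stayed 0 without each library. In LZ, 0 became 1 with library size only, 42 with the Wald test, 54 with read counts, 7 with a surrogate variable, 23 with GC trends removed and 0 to 5 without each library. For the difference of zone effects it was 0 by edgeR under each alternative run, with 384 at an unadjusted p under 0.05.

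With an estimated correlation the lists past the threshold went from 11, 7, 13, 3 and 8, in the order of the report, to 2, 0, 2, 0 and 0, and with exact permutation of list means to 0 in each of the 4 comparisons so tested. This 0 says little about the lists: in the SykY317F zones no list could pass, and in the others 14 of 24 would have needed the smallest possible exact p (0.0286). Thinning gave 8 in DZ and 4 for the difference of zone effects, and read counts 5 in LZ. Without each library they ran from 10 to 14, 7 to 10, 7 to 14, 3 to 5 and 5 to 9. The ribosomal list median in DZ turned to -0.028 without the libraries under 400000 UMIs and ran from -0.049 to 0.25 without each library, that of the early response from -0.055 to 1.12, and that of the ribosomal list for the difference of zone effects from -0.030 to 0.42.

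The zone score difference in LZ turned to 0.93 with the G2 and mitosis list in place of the DZ list, 0.017 with members of at least 20 counts and 0.34 with read counts. The difference of zone differences turned to 0.29 with the G2 and mitosis list, and the DZ difference was 0.44 with members of at least 20 counts (exact permutation p = 0.0286). Without each library the scores ran from 1.15 to 1.35 in WT, 0.58 to 1.15 in SykY317F, 0.07 to 0.55 in DZ, -0.32 to 0.24 in LZ and -0.68 to -0.10 for the difference. The slopes ran from 0.37 to 0.59 over all genes and from 0.44 to 1.01 over the list genes. Thinned to 149641 UMIs, the difference of zone differences had a median of -0.54 and a median permutation p of 0.109 over 21 draws (0.000816 to 0.390, under 0.05 in 5), and the full counts of the members kept gave -0.60 (permutation p = 0.0408, under 0.05 in 11), so the choice of members moves it.

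Genes that did not pass and changed sign were these. Syk in LZ turned to 0.011 with the stricter filter, 0.0011 with both groups alone, 0.023 without both libraries with the fewest UMIs, 0.061 with GC trends removed and from -0.12 to 0.070 without each library, and in DZ to -0.0023 with read counts and from -0.034 to 0.15 without each library. Cbl turned to 0.54 in the SykY317F zones and 0.38 in LZ with read counts, and without each library ran from -1.44 to 0.024 in the SykY317F zones. Its difference of zone effects was -0.0057 with library size only, -0.44 without both libraries with the fewest UMIs and -0.74 to 0.73 without each library. Cblb with limma voom turned to 0.50 in the SykY317F zones and 2.09 for the difference, and without each library ran from -1.97 to 1.33, from -1.23 to 2.07 and, in LZ, from -1.99 to 0.53. Cxcr4 in the SykY317F zones was -0.17 without both libraries with the fewest UMIs and -0.21 to 0.40 without each library. For the difference of zone effects Cd83 was -0.0041 with library size only, -0.032 without both libraries with the fewest UMIs and -0.084 to 0.46 without each library, and Rgs13 was -0.37 without those libraries, -0.18 with a surrogate variable and -0.93 to 4.22 without each library. Rpl10a in DZ was -0.075 with read counts.

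Same-numbered libraries of both zones had deviations correlated from -0.56 to 0.21, and 5 of 12 correlated best with their own number, so the rule set for pairs was not met. Same-numbered libraries of the other genotype had a mean correlation of 0.041 in 1 zone (4 pairs, -0.17 to 0.18) and 0.188 across zones (4 pairs, 0.043 to 0.31, against -0.039 for differently numbered ones), so whether 1 number is 1 mouse stays open. With the replicate block the SykY317F zones had 1 gene, LZ 6 lists, the WT zone score 1.29 (exact permutation p = 0.25, the smallest possible with 3 pairs) and Cbl a difference of zone effects of -0.51. With the replicate block within genotype the WT zones had 1 gene and the SykY317F zones 0, Cbl had 0.16 in the WT zones and -0.66 for the difference, and Cd83 -0.025 for the difference.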

Other observations

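The values here were chosen only after the results were seen, and no test was added for the uneven UMI counts. Trim12c had 1398 and 1676 UMIs in SykY317F DZ replicates 1 and 4, and 73 UMIs or fewer in each of the other 12 libraries. Scgb1a1 and Sftpc, genes known from lung epithelium, had 78 and 54 UMIs in SykY317F DZ replicate 4 and at most 12 in each other library. Scaled to the UMI total, these were 204 and 141 CPM. The shallow SykY317F LZ libraries were also raised on that scale, with Scgb1a1 at 26.4, 29.7 and 26.7 CPM and Sftpc at 15.8, 14.9 and 33.4 CPM. In all remaining libraries Scgb1a1 was at most 8.50 and Sftpc at most 9.24 CPM. Rpl15 and Zfp422 had 0 UMIs in the 3 SykY317F LZ libraries and 4 to 51 in each other library. With GC trends removed, an alternative added after seeing the data, 17 genes were higher and 6 lower in SykY317F LZ than in WT LZ, and 3 of the 17 were in the ribosomal protein list.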
